A study of Mus musculus with 6 samples.

How the data were processed

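The data were 6 single-colour expression arrays of RNA labelled as from spermatogonia of mice 1 week old, 1 wild-type and 1 Zfp145 knockout array on each of 3 chips. The groups were taken from the sample titles. The labels do not say whether the 3 chips of a genotype received the same RNA extract, nor how many animals contributed. The values were used as the authors deposited them, as linear intensities per probe set, all above 0. The software and the background correction behind these intensities are not given in the sources used here. The mean after removing the lowest and highest 2% of values was 500.3 on both U74Av2 arrays, 500.1 on both U74Bv2 arrays and 500.3 on both U74Cv2 arrays, so the deposited intensities had been scaled array by array. No detection calls or scanner files were used.

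Gene names came from a table that pairs probe sets with GEO's platform annotation. On U74Av2 10833 probe sets had 1 gene symbol, 396 several and 1193 none. On U74Bv2 these were 10581, 178 and 1652, and on U74Cv2 7717, 150 and 4001. Probe sets with several symbols were not named. Entrez identifiers were matched to a RefSeq gene table of the assembly GRCm38.p6 for 10817, 10550 and 7677 of the probe sets with 1 symbol, and no symbol changed. The arrays name no genome build, so no coordinates are given. That table served only for names, gene span and which genes neighbour each other.

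Each chip was processed on its own. The 66 control probe sets of each chip were set aside. The null array was divided by the median ratio of null to wild type over the probe sets in the upper part of mean rank, a log2 shift of 0.01 on U74Av2, 0.00 on U74Bv2 and 0.02 on U74Cv2. A floor was then set at the 40th percentile of the scaled values of both arrays, at 98.3, 165 and 124. Values under it were raised to it, and log2 of null over wild type was taken. A probe set at the floor on 1 array gives a bound on its fold, and one at the floor on both gives none. No test was made, since each genotype had 1 array per chip, and differences of at least 2-fold were counted. The floor, the threshold and the lists were fixed before the data were examined.

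The only repeated measurement is that some genes have several probe sets. The spread was the scaled median absolute difference of log2 ratios between probe sets of the same gene on the same chip, divided by the square root of 2. It was 0.43, 0.21 and 0.14 at low, middle and high level on U74Av2, 0.36, 0.31 and 0.24 on U74Bv2, and 0.65, 0.46 and 0.31 on U74Cv2. It covers technical spread and differences between transcripts, and not the spread between animals. The ratio of 3' to 5' signal was between 2.72 and 3.15 for Actb and between 1.14 and 1.28 for Gapdh over the 6 arrays.

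The genes named were chosen by a fixed rule. They were Zfp145, then the 6 largest ratios in each direction on U74Av2 and the 3 largest in each direction on U74Bv2 and U74Cv2. These were taken among probe sets with 1 established symbol, above the floor on both arrays and with a brighter value at or above the chip's 75th percentile. Added were the 3 brightest genes in each direction at the floor on 1 array and at least 4-fold above it on the other. For each list up to 4 members at least 2-fold different were named, or else the 2 brightest. For gene lists, each gene was represented by its probe set of the highest level percentile within its chip. Members of a list include genes at the floor on 1 array, at their bound. Of 795 genes in the 28 lists 790 were matched. Random lists were matched on chip and on 10 level bins, and 95% intervals of medians came from 2000 bootstrap draws over members. Lists share some genes, so they are not independent of each other.

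The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with 200 genes changed 4-fold on each chip. On U74Av2, with 12422 probe sets, 100% of the changed genes were recovered and 0.0655% of the others were called. On U74Bv2, with 12411 probe sets, these were 100% and 0.0737%, and on U74Cv2, with 11868 probe sets, 100% and 0.0257%. The simulated noise had the same size on every chip, and on U74Cv2 it lay below the spread between probe sets at every level. The others also include probe sets at the floor on both arrays, which cannot be called. These shares therefore do not give the rate of false calls on U74Cv2. The simulated noise does not stand for the spread between animals either. Of 200 lists of 20 genes drawn at random from the measured values, 185 lay inside the central 95%. They come from the same genes as the random lists, so this checks the calculation only. A list raised by 0.3 lay at the 99.99th percentile.

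Alternatives were the values as deposited, quantile normalization, loess of the ratio on level, floors at the 20th and 60th percentiles, no floor, thresholds of 3-fold and 1.5-fold, and only probe sets whose design marks no sharing between transcripts. For lists they were also the mean over a gene's probe sets, the median over all of a list's probe sets, U74Av2 alone, and the control probe sets taken as 0. Leaving out U74Cv2 and matching random lists on gene span were chosen after the data were seen.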

Results

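RNA labelled as total RNA of spermatogonia, the mitotic germ cells of the testis, was measured in mice 1 week old on a mixed 129 and C57BL/6 background. The comparison was between wild-type mice and mice with a knockout of Zfp145, a transcriptional repressor with a BTB domain and zinc fingers, now named Zbtb16 and also known as PLZF. It asks which transcripts differ in level when the gene is disrupted. Each genotype was hybridised to 1 array of each of 3 chips, U74Av2, U74Bv2 and U74Cv2, which carry different probe sets, so the 6 arrays hold no replicates. Every value is from a single array, no difference has a replicate check, and no p-value is given. The number of arrays limits the precision. After the control probe sets were set aside, the chips held 12422, 12411 and 11868 probe sets. Signal lay above the chip's floor on both arrays for 7082 of them on U74Av2, 6915 on U74Bv2 and 6280 on U74Cv2.

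Zbtb16, the targeted gene, had lower signal in the null array on both chips that measured it above the floor. On U74Av2 1 probe set read 770.2 in the wild type and 158.1 in the null, a log2 ratio of -2.29, or 4.90-fold lower. On U74Cv2 1 probe set read 1156.8 in the wild type and 510.8 in the null, a log2 ratio of -1.20, or 2.30-fold lower. Another probe set on U74Av2 read 50.6 and 16.7, both at or below the floor of 98.3, and gives no fold. The labels do not say which part of the gene was deleted, so a probe set outside that part would not check the genotype. With the floor at the 60th percentile of the chip, the first ratio was a bound of -1.38.

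On U74Av2 26 probe sets were at least 2-fold higher in the null array and 45 at least 2-fold lower, which loess on level turned into 32 and 34. Among the brighter probe sets the largest ratio upward was that of Sart3, an RNA-binding factor of spliceosome recycling, at 1.18 on the log2 scale. Ccnd2, the cell cycle regulator cyclin D2, read 1122.9 in the wild type and 2412.9 in the null, a log2 ratio of 1.09. Nedd4l, a ubiquitin ligase, stood at 1.05, Pfdn6, a subunit of the prefoldin chaperone, at 0.88, Gsto1, a glutathione transferase, at 0.85, and Ythdc1, a reader of methylated adenosine in RNA, at 0.82. After Zbtb16, the lowest ratio was that of the histone gene H3c14 at -1.59, which read 1859 in the wild type and 621.8 in the null. Nr2f2, the orphan nuclear receptor COUP-TFII, stood at -1.35, the homeobox gene Rhox5 at -1.04, Ccndbp1, a cyclin D1 binding protein, at -1.04, and Wdtc1 at -1.02. The spread between probe sets of the same gene was 0.14 at high and 0.21 at middle level on this chip. A second measured probe set of Sart3 gave -0.22, while that of Nr2f2 gave -0.54 and that of Pfdn6 0.22. The 3 others of Nedd4l gave 0.57, 0.60 and -0.05.

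On U74Bv2 65 probe sets were at least 2-fold higher in the null array and 80 at least 2-fold lower. The 3 largest ratios upward among the brighter probe sets belonged to Zfp809, a zinc finger protein that represses retroviral DNA, at 1.63, to Rhot2, a mitochondrial GTPase, at 1.29, and to Mxra7 at 1.10. The 3 largest downward belonged to Acp5, the tartrate-resistant acid phosphatase of osteoclasts and macrophages, at -1.47, to Mogat2, an acyltransferase of triglyceride synthesis, at -1.23, and to Cacng5, a calcium channel gamma subunit, at -1.17. Other probe sets did not bear out all of these sizes. Those of Zfp809 gave -0.51 and -0.54, those of Rhot2 gave -0.10 and 0.29, that of Mxra7 gave 0.28 and that of Acp5 gave -0.21.

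On U74Cv2 452 probe sets were at least 2-fold higher in the null array and 436 at least 2-fold lower. Aifm3 stood at 2.51, Tox, a transcription factor of lymphocyte development, at 2.42, and Ttc1 at 2.39. Gchfr, the feedback regulator of GTP cyclohydrolase, read 14107.1 in the wild type and 1645.2 in the null, a log2 ratio of -3.12. The RNA-binding protein Celf1 stood at -2.46 and the phosphatase Dusp15 at -2.33. Other probe sets of the first 3 genes gave 0.47 for Aifm3, 0.07 and 0.17 for Tox, and 0.39 for Ttc1. For the genes on the lower side they went upward, at 0.30 and 0.27 for Gchfr, 0.03, 0.13, 0.78 and 1.19 for Celf1, and 0.41 for Dusp15.

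Genes at the floor on 1 array give only a bound. The brightest of these on the higher side were Polr2f, a subunit of the RNA polymerases, at least 8.43-fold higher in the null array, Mirg at least 6.38-fold and the tyrosine kinase Fes at least 5.29-fold. On the lower side Ppil6 was at least 15.5-fold lower, Cdc37l1 at least 14.6-fold and Rnf32 at least 5.73-fold. All 6 were measured on U74Cv2. The other measured probe sets averaged -0.03 on the log2 scale for Polr2f, 0.21 for Mirg, -0.23 for Cdc37l1 and -0.11 for Rnf32.

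**Figure D1:**
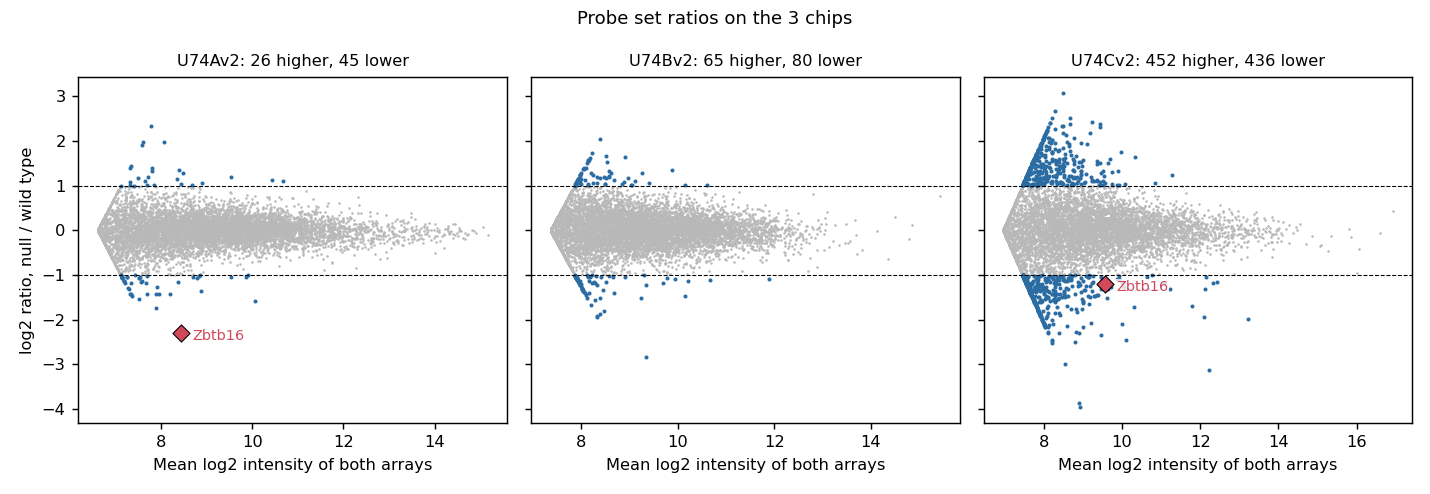
Log2 ratio of null to wild type against the mean log2 intensity of both arrays, after the floor, with 1 point per probe set above the floor on at least 1 array and 1 panel per chip. Blue points are at least 2-fold different (dashed lines), and diamonds mark the Zbtb16 probe sets at -2.29 on U74Av2 and -1.20 on U74Cv2.

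The share of probe sets at least 2-fold different, among those above the floor on at least 1 array, was 0.908% on U74Av2, 1.82% on U74Bv2 and 11.2% on U74Cv2. Other probe sets of the same genes showed how far these differences hold within the data. On U74Av2 they went the same way on average for 20 of 30 probe sets (66.7%, 95% exact binomial interval 47.2% to 82.7%). On U74Bv2 this was 37 of 69 (53.6%, 41.2% to 65.7%), and on U74Cv2 160 of 320 (50%, 44.4% to 55.6%). These intervals treat probe sets as independent, though some genes, Celf1 and Srcap among them, enter with more than 1. The other probe sets went the same way by at least 1.5-fold on average for only 4 of 30 on U74Av2, 2 of 69 on U74Bv2 and 13 of 320 on U74Cv2. The targeted gene Zbtb16 was itself among those on U74Av2 and on U74Cv2. So was Foxq1, at -1.42 on U74Av2 and -1.27 on U74Cv2, a gene the naming rule did not pick and singled out after the values were seen. Among the genes named here for their brightness and ratio on the 3 chips, 15 of 24 had another measured probe set. In 10 it went the same way on average. Of the 24, 8 rest on probe sets whose names carry a suffix, which can mark sharing between transcripts. Across genes measured on 2 chips, the log2 ratios correlated weakly. Pearson's r was 0.07 and Spearman's rho 0.11 over 989 genes on U74Av2 and U74Bv2, 0.14 and 0.10 over 992 genes on U74Av2 and U74Cv2, and 0.06 and 0.07 over 1153 genes on U74Bv2 and U74Cv2. These are correlations across genes, which are not independent replicates.

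**Figure D2:**
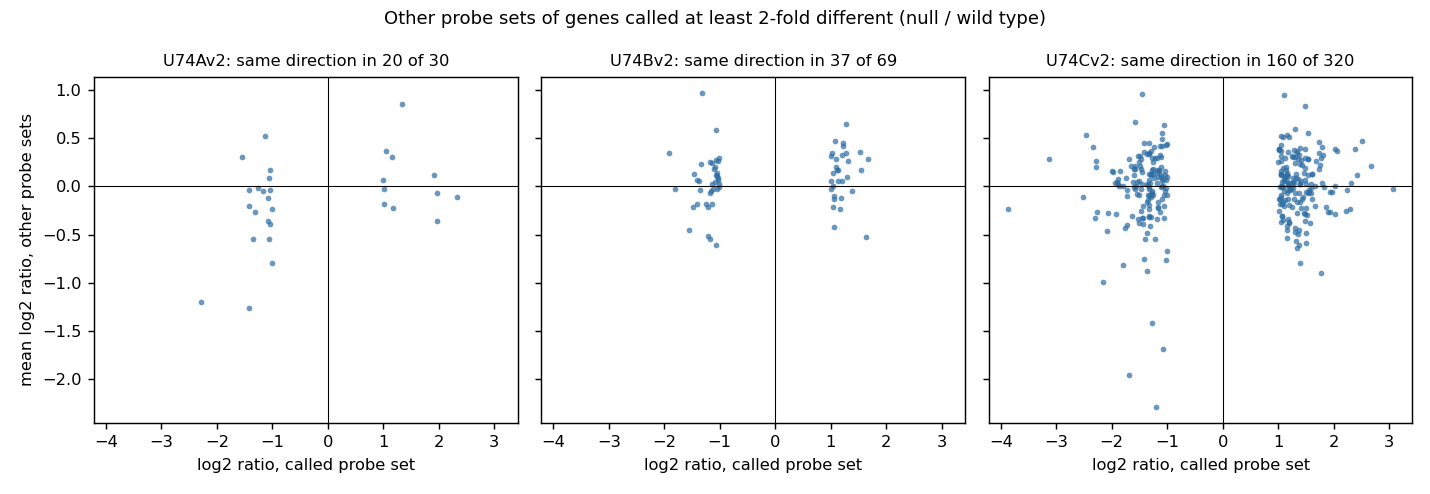
Mean log2 ratio of a gene's other measured probe sets (vertical) against the log2 ratio of the probe set that was at least 2-fold different (horizontal), null over wild type, 1 point per probe set and 1 panel per chip. Points in the upper right and lower left go the same way, 20 of 30 on U74Av2, 37 of 69 on U74Bv2 and 160 of 320 on U74Cv2.

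Groups of genes were compared as 28 lists fixed before the data were examined, each by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on chip and level. Medians outside the central 95% were found for 10 lists, 7 higher and 3 lower in the null array, where 1.4 would be expected if 5% of lists fell outside by chance. Of 200 lists drawn at random from the measured genes, 185 lay inside the central 95%. They share their source with the random lists, so they check only the calculation. Random lists ignore that genes of a pathway vary together, so a percentile describes these arrays and is no test of genotype. Of the 10 lists outside the central 95%, the spermatogonial list had a bootstrap interval over members that held 0, at -0.06 to 0.36. So did the fibroblast and matrix (-0.06 to 0.41), histone deacetylase and corepressor (-0.14 to 0.23) and BTB zinc finger (-0.0049 to 0.48) lists.

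Genes of spermatogonial stem and progenitor cells had a median of 0.20 over 24 measured members (99.4th percentile), with 16 ratios above 0. Bcl6b, a GDNF-induced factor of stem cell maintenance, was at least 2-fold higher, at 1.16. This rests on a single dim probe set on U74Cv2, at 160.7 in the wild type and 365.3 in the null against a floor of 124, where the spread was 0.65. Neither of its 2 other probe sets was measured above the floor on both arrays. Zbtb16 itself, the pluripotency factor Pou5f1 and the zinc finger gene Sall4 were at least 2-fold lower. Sall4 stood at -1.32 on U74Cv2, but at 0.27 and 0.63 in its other probe sets. Pou5f1 was at the floor in the null on U74Cv2, a bound of -1.19, and stood at 0.17 on U74Av2. Because of these low members the mean of the list was 0.04. Without U74Cv2, a setting chosen after the data were seen, the median was 0.30. With the floor at the 20th percentile it was 0.13 and inside the random lists.

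Genes of differentiating spermatogonia had a median of 0.08 over 12 members, at the 85.7th percentile. Ccnd2 was at least 2-fold higher, and Prss50, a testis protease, was at least 2.37-fold lower with the null array at the floor. General germ cell genes had a median of 0.05 over 19 members, at the 81.6th percentile, and none was 2-fold different. Its brightest members were Mov10l1, an RNA helicase of the piRNA pathway, at 0.05 and Tex101, a germ cell surface protein, at -0.53. Another probe set of Mov10l1 gave -0.64. Both lists depended on the chip. Without U74Cv2 the median of the differentiating list was 0.21 over 10 members (99.1st percentile) and that of the germ cell list 0.30 over 13 members (99.97th percentile).

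Meiosis genes had a median of -0.15 over 20 members, at the 7.19th percentile. The brightest were the cohesin subunit Stag3 at -0.24, with 0.13 in another probe set, and the synaptonemal complex gene Syce1 at -0.44. Without U74Cv2 the median was -0.01, and with the floor at the 60th percentile it was -0.24 and outside the random lists. Of 25 spermatid genes on the arrays only 11 were above the floor on at least 1 array. The spermatid list had a median of 0.15 over these 11, at the 89.8th percentile and so inside the random lists. Whether the samples held spermatids was not tested. Of its brightest members the acrosomal genes Acr stood at 0.72 and Izumo1 at -0.30, and without U74Cv2 the median turned to -0.25 over 6 members.

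The RNA labelled as from spermatogonia also gave strong signal for somatic genes. On U74Av2 the Sertoli list genes Clu and Aard lay at the 99.6th and 99.5th level percentiles, beside the germ cell gene Dazl at the 98.0th. No list median can therefore be assigned to spermatogonia alone. Genes of the somatic cells of the testis went different ways. Sertoli cell genes had a median of -0.12 over 31 members, with 21 ratios below 0, at the 3.06th percentile. Rhox5 was at least 2-fold lower, and so was Tsx, at -1.02. Tsx rests on 1 dim probe set, at 296.3 in the wild type and 146.9 in the null, where the spread was 0.43. The Sertoli median lay inside the random lists. It lay outside them with U74Av2 alone, after quantile normalization, after loess, with the floor at the 60th percentile, with the probe sets of plain design alone and with the control probe sets taken as 0, at medians between -0.13 and -0.16. Macrophage genes had a median of -0.16 over 16 members, at the 2.03rd percentile. None was 2-fold different, and the brightest were Laptm5 at -0.45 and the fractalkine receptor Cx3cr1 at -0.14. The median lay inside the random lists after quantile normalization, at -0.15, with the floor at the 20th percentile, at -0.14, and with the probe sets of plain design alone, at -0.15. The erythroid list had 5 members, all below 0, and a median of -0.46 (2.36th percentile). Its brightest member was the alpha globin gene Hba-a1, at 4424.1 in the wild type and 2697.2 in the null. That median lay inside the random lists in 4 of the 6 settings that gave it a value.

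Fibroblast and matrix genes had a median of 0.13 over 26 members, at the 98.9th percentile. The matrix protein gene Postn was at least 2-fold higher, at 1.29, and Igfbp7, a secreted growth factor binding protein, at least 2.10-fold lower with the null array at the floor. Leydig cell genes had a median of -0.16 over 12 members, at the 4.74th percentile. Within that list Hsd17b3, an enzyme of testosterone synthesis, stood at 1.20 and Thbs2 at 1.06, against the direction of the median. Hsd17b3 rests on 1 dim probe set, at 138.4 in the wild type and 320.3 in the null, where the spread was 0.43. Thbs2 rests on 1 probe set on U74Cv2, and no other was measured above the floor on both arrays. With U74Av2 alone the median of the Leydig list was -0.24 over 10 members, at the 1.01st percentile. Peritubular myoid genes had a median of 0.04 over 11 members, with the contractile genes Mylk at -0.37 and Acta2 at -0.11. Another probe set of Acta2 gave 0.67. Endothelial genes had a median of 0.02 over 14 members, with Eng at 0.12 and Egfl7 at -0.36. Neither list stood apart from random lists.

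**Figure D3:**
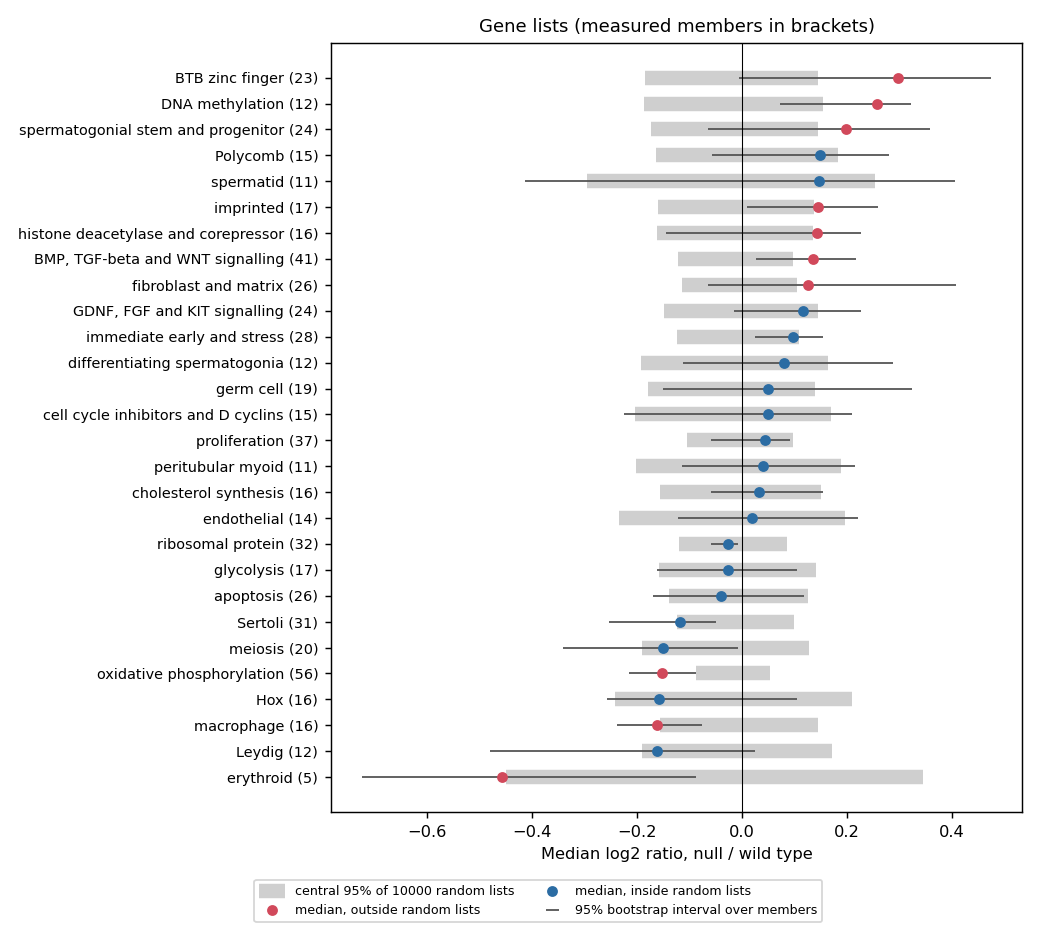
Median log2 ratio of null to wild type for each of the 28 gene lists (points), with the 95% bootstrap interval over members (lines) and the central 95% of 10000 matched random lists (grey bars). Red points lie outside the grey bars, from the erythroid list at -0.46 to the BTB zinc finger list at 0.30.

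Genes of oxidative phosphorylation, the nuclear-encoded subunits of the mitochondrial respiratory chain and ATP synthase, had a median of -0.15 over 56 measured members, with 47 ratios below 0. The bootstrap interval over members was -0.21 to -0.09, and the median lay at the 0.05th percentile of random lists. Cox6b1 was at least 2-fold lower, at -1.19. This rests on a single dim probe set on U74Av2, at 308.5 in the wild type and 136 in the null, where the spread was 0.43. Neither of the 2 other Cox6b1 probe sets was measured above the floor on both arrays. The median lay outside the random lists in all 11 settings that gave a percentile. Medians of similar size were found for the Sertoli (-0.12), meiosis (-0.15), macrophage (-0.16) and Leydig (-0.16) lists, and the 18S rRNA controls had a median of 0.46 on each chip. The bacterial and phage transcripts added as hybridization controls had medians of 0.24 to 0.29 over the chips. Glycolysis genes had a median of -0.03 over 17 members, with the hexokinase Hk1 at 0.39 and the aldolase Aldoa at 0.08. Ribosomal protein genes had a median of -0.03 over 32 members, with Rpl41 at -0.11 and Rps20 at -0.05, and turned to 0.02 after loess. Cholesterol synthesis genes had a median of 0.03 over 16 members, with Fdps at 0.02 and Mvd at 0.01.

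DNA methylation genes had a median of 0.26 over 12 members, with 10 ratios above 0, at the 99.9th percentile. The brightest were the maintenance methyltransferase Dnmt1 at 0.12 and the de novo methyltransferase Dnmt3b at 0.31. With U74Av2 alone the median was 0.12 over 9 members and inside the random lists. The spermatogonial list (0.20), the 18S rRNA controls (0.46) and the added hybridization controls (0.24 to 0.29) were higher in the null array too. The macrophage list (-0.16) was lower. Histone deacetylase and corepressor genes had a median of 0.14 over 16 members (97.9th percentile), although the brightest, Sin3b and Hdac6, stood at -0.28 and -0.18. That median lay outside the random lists in 6 of 10 settings. The BTB zinc finger genes, the family of Zbtb16, had a median of 0.30 over 23 members, at the 99.99th percentile. Zbtb16 and, from its dim probe set on U74Cv2, Bcl6b were its members at least 2-fold different, and with U74Av2 alone the median was -0.00 over 13 members. Polycomb genes had a median of 0.15 over 15 members, at the 94.2nd percentile, with Cbx2 at 0.61 and Eed at 0.11. Hox genes had a median of -0.16 over 16 members, at the 10.5th percentile, with Hoxa4 at -1.06.

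Signalling genes of the BMP, TGF-beta and WNT pathways had a median of 0.14 over 41 members, with 28 ratios above 0, at the 99.6th percentile. Beside it stood the fibroblast and matrix (0.13), spermatogonial (0.20), Sertoli (-0.12) and macrophage (-0.16) lists, and the 18S rRNA controls at 0.46 on each chip. The added hybridization controls stood at 0.24 to 0.29. The receptor gene Bmpr1b was at least 3.07-fold higher with the wild type at the floor, and Wnt4 stood at 1.11. Wnt4 rests on 1 probe set on U74Cv2, where the spread was 0.46, and no other was measured above the floor on both arrays. Genes of GDNF, FGF and KIT signalling, which maintain spermatogonia, had a median of 0.12 over 24 members, at the 94.4th percentile, with Src at 0.23 and Pik3r1 at -0.14. Another probe set of Pik3r1 gave 0.79. That median was -0.06 over 15 members with U74Av2 alone, and 0.20 and outside the random lists with the mean over each gene's probe sets. Imprinted genes had a median of 0.15 over 17 members (98.0th percentile), with the brightest, Gatm and Gnas, at -0.29 and -0.13. Another probe set of Gnas gave 0.52. Their median lay outside the random lists in 5 of 10 settings. It was 0.04 both without U74Cv2 and with U74Av2 alone, and 0.08 with the mean over each gene's probe sets, inside the random lists each time.

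Proliferation genes did not stand apart, with a median of 0.04 over 37 members at the 80.8th percentile. Kif11, a mitotic motor, was at least 3.68-fold lower on U74Cv2 with the null array at the floor, while its probe set on U74Av2 stood at 0.08. Cell cycle inhibitors and D cyclins had a median of 0.05 over 15 members, at the 77.5th percentile, and Ccnd2 was the member at least 2-fold different. With U74Av2 alone that median was -0.02. Apoptosis genes had a median of -0.04 over 26 members, with the survival factor Mcl1 at -0.08 and Aifm1 at 0.39. Immediate early and stress genes had a median of 0.10 over 28 members, at the 96.1st percentile, and the small heat shock gene Hspb1 was at least 2.97-fold higher with the wild type at the floor. Over the 12 cell type lists together, 5 of 200 measured markers were at least 2-fold higher in the null array and 7 at least 2-fold lower.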

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

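Control probe sets lie outside the comparisons and were higher in the null array on each chip. They were listed above a median log2 ratio of 0.1, a limit chosen after their values were seen. The 18S rRNA probe sets had a median log2 ratio of null over wild type of 0.46 on U74Av2, 0.46 on U74Bv2 and 0.46 on U74Cv2, and all 9 were higher in the null. The bacterial and phage transcripts added as hybridization controls had medians of 0.27 on U74Av2, 0.24 on U74Bv2 and 0.29 on U74Cv2, and 26 of 27 were higher in the null. With the control probe sets taken as 0, the median of all genes moved by -0.20.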

How the results depend on the processing

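No paired analysis was possible because each genotype had 1 array per chip. Counts of probe sets depended on the floor and the threshold by construction. In the order higher and lower on U74Av2, U74Bv2 and U74Cv2, the floor at the 20th percentile gave 201, 481, 493, 505, 977 and 1083 probe sets. The floor at the 60th percentile gave 4, 10, 7, 11, 92 and 91. No floor gave 570, 1318, 1075, 1070, 1375 and 1636. At least 3-fold gave 4, 3, 5, 6, 108 and 98, and at least 1.5-fold gave 257, 317, 470, 443, 1087 and 1104. Probe sets whose names carry no suffix, a smaller set, gave 16 higher and 28 lower on U74Av2 and 283 lower on U74Cv2. Every other setting moved these counts by less than 1.5 times. The Zfp145 ratio on U74Av2 was -1.38 with the floor at the 60th percentile, where the null lay at the floor, and moved by less than the spread in the other settings.

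List medians left their bootstrap interval in 5 cases, whose cause was not tested. With U74Av2 alone the germ cell list was at 0.37 and the GDNF, FGF and KIT list at -0.058. Of the lists outside the random lists, only the BTB zinc finger list turned sign, to -0.0049 with U74Av2 alone, on the lower bound of its interval, and the cause was not tested. Lists inside the random lists also turned sign in some settings, namely spermatid, endothelial, cell cycle inhibitors and D cyclins, GDNF, FGF and KIT, and ribosomal protein. The ribosomal protein list was at -0.0017 after quantile normalization, 0.017 after loess and -0.066 with the control probe sets taken as 0. In that last setting the median of all genes moved by -0.20, and list medians are given relative to it. Leaving out U74Cv2 was chosen after the data were seen. The erythroid list had too few members for a value in 4 settings. Of 380 values for the other named genes 356 moved by less than the spread, 24 moved further and none reversed. The signal over the floor limits what can be read from dim probe sets.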

Other observations

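All tests of explanations were chosen after the results they bear on were seen. A first pattern is that U74Cv2 had many more probe sets at least 2-fold different than the other chips. Sharing between transcripts that the names mark is argued against as the source, since probe sets without a suffix were 2-fold different in 11.7%. On U74Av2 and U74Bv2 such probe sets were 2-fold different in 0.691% and 1.66%. Probe sets with any suffix, which can but need not mark sharing, stood at 10.1% on U74Cv2, so they do not isolate shared ones. Genotype as the source of most of these differences is argued against too. Other probe sets of the same genes went the same way for 50% of the called probe sets. The interval, 44.4% to 55.6%, lay below the 70% set as a limit after the value was seen. It treats probe sets as independent, though some genes enter with more than 1. A share of 50% is what measurement noise on the chip predicts, and noise is a candidate explanation for most of the differences. Which single probe sets differ with genotype stays open.

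A second pattern is the lower median of the oxidative phosphorylation genes. Gene span is argued against, as the median lay at the 0.09th percentile of random lists matched on span as well as level. After loess the median lay at the 0.36th percentile. Random lists were already matched on level, so a bias that follows level would move them too, and this test could hardly decide. Noise of U74Cv2 is argued against by the 0.43rd percentile without that chip. Lists of other cell types had medians of similar size, at -0.12 for Sertoli, -0.16 for macrophage and -0.16 for Leydig genes, and the 18S rRNA controls stood at 0.46 on each chip. The added hybridization controls stood at 0.24 to 0.29. No test run here separates genotype from a difference between the RNA extracts or the cells in them, so both stay open.

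A further, weaker pattern is a spermatogonial list with a median above 0 beside Sertoli and macrophage lists with medians below 0. The Sertoli median lay inside the random lists, at the 3.06th percentile, and the macrophage median lay inside them in 3 of 10 alternative settings. Fewer somatic cells of every kind in the null sample would lower the fibroblast and matrix list too. Its median exceeded that of the Sertoli list by 0.24 (0.05 to 0.55), so the medians of these lists did not fall together in these arrays. That interval runs over genes of single arrays and not over samples. The interval of the fibroblast and matrix median itself, -0.06 to 0.41, held 0, so the number of somatic cells is not settled. Of 6 pairs of lists compared, 4 had an interval above 0 with all chips and 5 without U74Cv2. The peritubular myoid median exceeded the Sertoli median by 0.16, with an interval of -0.0023 to 0.41 with all chips and 0.02 to 0.36 without U74Cv2. The interval for the germ cell list against the Sertoli list held 0 both ways. A bias that follows level is argued against for the Sertoli list by its median of -0.13 after loess, beside -0.12 before. Its 1.32nd percentile after loess adds little, since random lists were already matched on level. Other lists hold 5 of the 24 spermatogonial, 2 of the 31 Sertoli, 0 of the 16 macrophage and 1 of the 26 fibroblast and matrix genes. A change in the mix of Sertoli cells, macrophages and germ cells, or in their transcripts, may be behind the pattern and was not tested.

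B2m and genes of MHC class I were looked at as 1 of 17 families of gene symbols and were chosen after their values were seen. B2m read 4165.5 in the wild type and 2262.9 in the null, a log2 ratio of -0.89, with H2-K1 at -0.60 and H2-K2 at -0.79. Others went the opposite way, with H2-Q2 and Tap2 at 0.64 and H2-M10.1 at least 2-fold higher, with the wild type at the floor. The other measured probe set of H2-M10.1 gave -0.36. Of 18 measured genes 11 had ratios below 0 and 7 above, and none was 2-fold lower. Their median was -0.17, at the 3.31st percentile and so inside the random lists. Fewer macrophages in the null sample could neither be supported nor excluded, since the macrophage median exceeded that of these genes by 0.0093 (-0.36 to 0.32). Probes shared between the paralogs stay open too, with a median of -0.15 (-0.89 to 0.64) over B2m, Tapbp, Tap1 and Tap2. That interval only spans the lowest of the 4 values (B2m) and the highest (Tap2), so it could hardly decide. Of the 18 genes 13, with H2-K1 and H2-K2 among them, rest on probe sets with a suffix, which can but need not mark sharing. Tap2, which is no class I heavy chain gene, is also among the 13.

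DNA of the strain in which a gene was targeted may stay around it in a knockout on a mixed background. Of the 100 measured genes nearest to Zbtb16 in gene order, 11% (5.62% to 18.8%) were at least 1.5-fold different, against 11.7% of all others. The interval is wide enough that neither an excess nor its absence can be read from it.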
